A study of Homo sapiens with 2 samples.

How the data were processed

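C4-2B cells treated with DMSO vehicle or 2.5 µM MA4-022-1 were compared, with 1 library per group, and the exposure time is not given in the sources used here. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into ScriptSeq libraries that were sequenced as single 50 bp reads on a HiSeq. Per the submitters' processing notes, TopHat2 2.0.13 and Cufflinks 2.2.1 were used with hg19. The authors deposited, for each library, a table of RPKM per gene with a locus and a symbol, and per the file headers the value is RPKM, so these are normalised values and no count test was run. The design had foreseen the sister unit of Cufflinks, and the same rule was applied to RPKM.

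Each table held 62271 rows in the same order. Of these, 2751 had no symbol and were left out of the gene counts. They held 29.6% of the summed RPKM in the vehicle library and 23.3% in the MA4-022-1 library. A further 1635 rows joined several symbols, 927 of them at 1 RPKM or more in a library, and stayed as genes of their joint name. Rows of one symbol were summed, which concerned 1397 of 15431 expressed genes. Short RNA symbols, which held 13.3% and 18.5% of the sums, were left out. All 33 rows named as the mitochondrial chromosome MT were at 0 in both libraries, so the list of mitochondrial genome genes gave no value. An exact 0 can be a failed estimate, so such values are described as listed at 0.

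A gene counted as expressed at 1 RPKM or more in at least 1 library. The measure was log2 of RPKM + 1 in the MA4-022-1 library over RPKM + 1 in the vehicle library, with a threshold of 2-fold. The deposited scale was kept because the median log2 ratio of genes with a mean of 1 RPKM or more was -0.03, within the limit of 0.1. Gene lists, 55 in all, were written from general knowledge before the data were examined, as were the alternatives and the rule for named genes. A list with at least 5 expressed members was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size matched in 10 bins of mean expression, and called outside the random range under 2.5 or over 97.5. That percentile describes these 2 libraries and is not a test of the conditions. Members found only in joint rows were left out.

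Named genes were a set fixed in advance that included MYC, BRD2, BRD3, KLK3, TMPRSS2 and HEXIM1, the 12 highest and 12 lowest ratios among genes with at least 5 RPKM in the higher library and a locus of at least 300 nt, and up to 4 members per list with the largest ratios, those with at least 5 RPKM first. Some genes that this rule names are not reported here. Other names were chosen after their values were seen and are marked so. KLK3 was read from the row joined with KLK2.

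Depth was estimated from the steps of low values. In processed pseudogenes of 600 to 6000 nt that had a locus to themselves, RPKM multiplied by length fell on whole multiples of 1 read. Of 256 values of up to 5 reads in the vehicle library 224, or 87.5%, lay within 2% of a whole step, and of 195 in the MA4-022-1 library 170, or 87.2%. The fit gave totals of 27131556 and 19917776 reads and effective lengths shorter than the transcript by 201 and 202 nt. Among 2395 rows under 0.2 RPKM in both libraries, the ratio of 1.36 between values of the libraries, which is that of 1 read in each, was the most common. For other genes, reads were estimated from the median length of the annotated transcripts of GENCODE release 29, used for lengths, gene types and snoRNA hosts alone, since its coordinates are of another build. Symbols of 10968 expressed genes matched it. Counting intervals at 95% come from 4000 draws, cover counting error only and assume that length, and PCR duplicates and the spread between cultures are not in them.

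Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Both steps were tested on simulated data for MA4-022-1 against vehicle, with reads drawn for 9833 protein-coding genes at the real levels and totals. Changes were simulated only in genes with a mean of at least 5 RPKM, so detection below that level was not tested. Of 100 such genes with a simulated log2 change of 1.5 either way and 100 with 2.5, 100% passed 2-fold in the right direction. The simulated changes lay beyond the 2-fold threshold, so detection near it was not tested. Of 9633 unchanged genes, 0 passed 2-fold. The draws held counting error only, without PCR duplicates, spread between cultures or reads split among overlapping features. That result is therefore no rate of false calls for the real libraries. Of 100 lists of unchanged genes, 5 lay outside the random range, about the share that the percentile limits themselves set. Alternatives were other pseudocounts, filters, scalings, thresholds and bins, with further ones chosen after seeing the data.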

Results

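Total RNA was profiled in C4-2B cells, an androgen-independent prostate cancer line derived from LNCaP that models castration-resistant disease growing in bone. Cells received DMSO as vehicle or 2.5 µM MA4-022-1, a compound that the labels describe as an inhibitor of both the BET bromodomain proteins and kinases. BET proteins, among them BRD2 and BRD3, bind acetylated chromatin and help RNA polymerase II to elongate. Each group held 1 library, so no difference below has a replicate check and no p-value is given. The stated purpose was to find genes that this kind of tumour needs for growth and that the compound affects. Values were RPKM per gene, and low values moved in steps that placed the normalising totals at 27131556 reads for the vehicle library and 19917776 for the MA4-022-1 library. At these totals, 1 read on a transcript of 2000 nt was worth 0.0205 RPKM in the vehicle library and 0.0279 RPKM in the MA4-022-1 library, and 3 reads were worth 0.0615 and 0.0838 RPKM. Differences are log2 ratios of RPKM + 1, MA4-022-1 over vehicle, and folds are on that scale, which understates the change of low genes. Coordinates are those of the deposited loci on hg19, which can span neighbouring genes.

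Genes of DNA replication, mitosis and the histone supply of S phase were mostly lower in the MA4-022-1 library, while the BET gene BRD2 and the nuclear RNA NEAT1 were higher. The lists of nucleolar, amino acid stress and p53 target genes had medians below the random range and those of sterol and fatty acid synthesis above it, although most members of these lists lay within 2-fold. Of 15431 expressed genes, 1189 were at least 2-fold higher and 1479 at least 2-fold lower, and the median log2 ratio was -0.02. Higher genes made up 44.6% of those beyond 2-fold. With the housekeeping controls set to 0, which shifted the median by 0.12, the counts were 1538 higher and 1157 lower, and the share of higher genes was 57.1%, so the balance between the directions depended on the scale. Among 9836 protein-coding symbols, 405 were higher and 934 lower, a share of 30.2% higher. Of 47 gene lists with at least 5 expressed members, 12 had a median below the range of expression-matched random lists and 6 above it. Lists of genes drawn at random would place about 2.4 outside. Members of a list can vary together and lists share members, so that number is no expectation for cultures treated alike.

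The 12 lowest and 12 highest ratios belonged mostly to rows named by clone or sequence accession. All 12 of the highest and 10 of the 12 lowest were listed at 0 in the other library, for which no fold is given. The highest was AL354896.1, listed at 0 in the vehicle library and at 264 RPKM with MA4-022-1, and the lowest was RP11-540K16.1, at 9109 RPKM in the vehicle library and listed at 0 with MA4-022-1. The 2 genes among them with values in both libraries were CD84, at 79.5 against 0.216 RPKM, and CDR1, at 199 against 2.47 RPKM. Of the 24 values, 14 recurred exactly in another row of the same library.

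The 49 expressed members of the list of G1/S and DNA replication genes had a median log2 ratio of -1.90, below all 10000 random lists, and 39 were at least 2-fold lower with none at least 2-fold higher. RRM2, a subunit of ribonucleotide reductase that supplies deoxynucleotides, stood at 158 RPKM in the vehicle library and 6.01 with MA4-022-1, a log2 ratio of -4.50 with a 95% counting interval from -4.62 to -4.38 (chromosome 2, 10262455 to 10271545). CDC6, which loads the replicative helicase at origins, was 15.3-fold lower at 105 against 5.93 RPKM. CDC45 and MCM10, which act in the same helicase, stood at 41.6 against 2.38 and 19.7 against 1.18 RPKM. In the list of G2/M and mitosis genes, 41 of 52 expressed members were at least 2-fold lower and the median was -1.47, again below all random lists. PBK, a mitotic kinase, was at 99.6 against 11.8 RPKM. NDC80, a kinetochore protein, was 7.61-fold lower, and HJURP, the chaperone of the centromeric histone, at 30.3 against 3.51 RPKM. The transcription factor MYBL2 was at 12.8 against 1.17 RPKM.

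Genes of homologous recombination and replication fork protection had a median of -1.18 over 38 expressed members, 25 of them at least 2-fold lower, and none of 10000 random lists lay lower. RAD51AP1 was 9.09-fold lower at 64.5 against 6.21 RPKM, and the BRCA1 partner BARD1 5.53-fold lower at 448 against 80.1 RPKM. The helicase BLM stood at 10.4 against 0.858 RPKM, and RMI2, of the same complex, at 11.4 against 0.866 RPKM. In the broader list of kinases, 9 of 40 expressed members were at least 2-fold lower and 3 higher, with a median of -0.22 at percentile 8.6 of the random lists. Its largest differences were those of WEE1, CDK1, AURKB and MELK, which act in G2 and mitosis and were 4.92-fold, 4.80-fold, 4.07-fold and 3.92-fold lower. The 30 kinases outside the cell cycle lists had a median of 0.01. TNK2, a non-receptor tyrosine kinase chosen after its values were seen, was 3.49-fold higher at 15.7 against 57.3 RPKM.

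Replication-dependent histone genes, whose messages are made in S phase and mostly lack a poly(A) tail, had a median of -1.71 over 40 expressed members, below all random lists. Of these, 26 were at least 2-fold lower and 2 at least 2-fold higher. HIST1H1B, a linker histone, was at 446 RPKM in the vehicle library and 13.5 with MA4-022-1, or 30.9-fold lower (chromosome 6, 27833724 to 27835391). HIST1H3B stood at 587 against 37.1 RPKM, HIST1H2AJ at 90.1 against 4.09 and HIST1H2AB at 84.7 against 4.37. The 2 members that were higher were HIST2H2BE, at 20.9 against 139 RPKM, and HIST1H4I, at 1.94 against 8.18 RPKM, the latter named after its values were seen. Copies of these genes are near identical, so reads could be split among them, and single members are uncertain. Without the filter on low values the median was -0.81, since members near 0 in both libraries then entered.

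**Figure D1:**
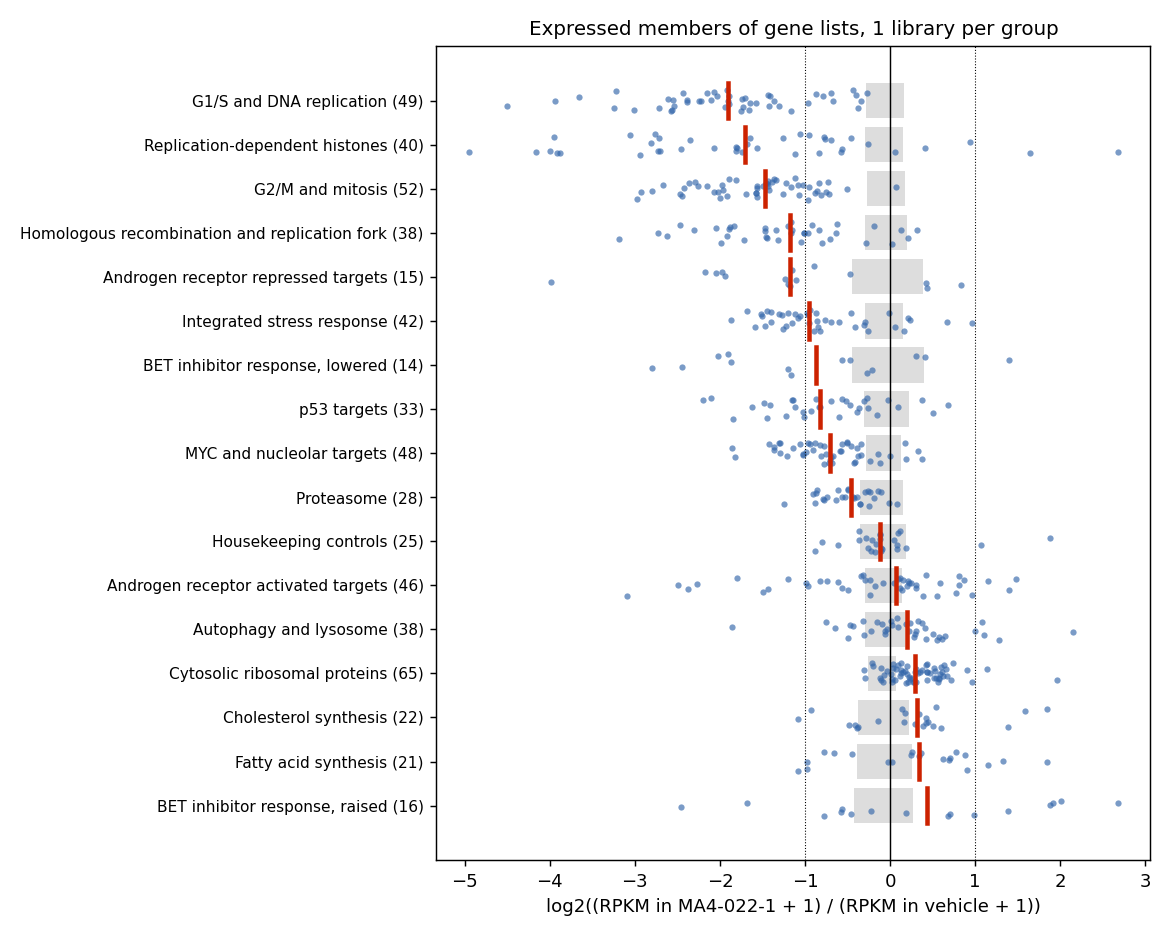
Log2 ratio of RPKM + 1, MA4-022-1 over vehicle, for each expressed member (blue points) of 17 gene lists, with the list median (red bar) and the central 95% of medians of random lists matched on expression (grey bar). Numbers in brackets are expressed members. The median of the G1/S list lies at -1.90 and that of the cholesterol list at 0.32, and dotted lines mark 2-fold.

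BRD2 was 3.77-fold higher with MA4-022-1, at 102 against 387 RPKM summed over its 8 rows, with a 95% counting interval for the log2 ratio from 1.88 to 1.95. BRD3 stood at 9.16 against 12.3 RPKM, within 2-fold. HEXIM1, the inhibitor of the elongation kinase P-TEFb that is often followed as a marker of BET inhibition, was 2.60-fold higher at 9.49 against 26.3 RPKM. Its symbol had 2 rows that went apart, at 5.08 against 23.2 and 4.41 against 3.07 RPKM. The list of genes known to be raised by BET inhibitors had a median of 0.43 over 16 expressed members, at percentile 99.7, with 5 at least 2-fold higher and 2 lower. HIST2H2BE, SAT1 and BRD2 led it, and SAT1, which acetylates polyamines, stood at 182 against 735 RPKM. The 2 lower members were the histone genes HIST1H2BJ, at 202 against 35.9 RPKM, and HIST1H2BC, at 308 against 95.3 RPKM, the latter chosen after its values were seen. Without the 7 members shared with the histone list the median was 0.98, whereas with single-row symbols alone, which drops BRD2, HEXIM1 and HIST2H2BE, it was -0.22. Without the member of largest change it was 0.19.

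MYC, a transcription factor whose gene is a common target of BET inhibitors, was 2.29-fold lower at 78.5 against 33.7 RPKM, with a counting interval of the log2 ratio from -1.29 to -1.11 (chromosome 8, 128747680 to 128753674). The list of genes known to be lowered by BET inhibitors had a median of -0.87 over 14 expressed members, at percentile 0.01, and 7 were at least 2-fold lower and 1 higher. That median was -0.57 without the member of largest change, -0.34 with a pseudocount of 5 and -0.24 without the filter on low values. HJURP, UBE2C, AURKB and E2F8 had its largest differences, and these are genes of the cell cycle. The 8 members outside the cell cycle lists had a median of -0.34, at percentile 13.5, within the random range. In the list of P-TEFb and the super elongation complex the median was 0.17, at percentile 88.6, with 2 of 16 members at least 2-fold higher. These were HEXIM1 and AFF1, a scaffold of that complex, at 4.18 against 9.83 RPKM. AFF4 and ELL2 were 1.82-fold and 1.47-fold higher.

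**Figure D2:**
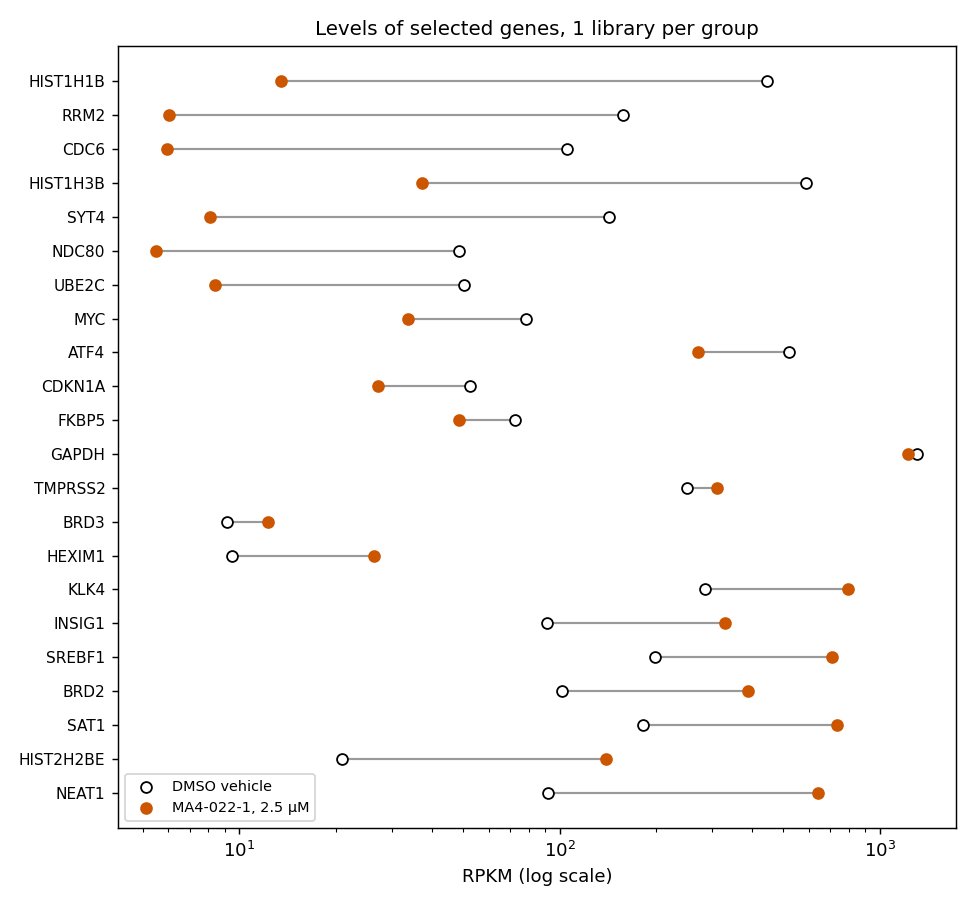
RPKM (log axis) of 22 genes in the vehicle library (open circles) and the MA4-022-1 library (orange circles), with a line joining the values of a gene, 1 library per group. HIST1H1B goes from 446 to 13.5 RPKM at the top and NEAT1 from 91.8 to 641 RPKM at the bottom, while TMPRSS2 and GAPDH lie within 2-fold.

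Genes of ribosome assembly and other MYC targets had a median of -0.71 over 48 expressed members, below all random lists, with 13 at least 2-fold lower and none at least 2-fold higher. PAICS, of purine synthesis, was at 104 against 28.2 RPKM, and NOP16, a nucleolar protein, at 96.6 against 26.5 RPKM. EIF5A, a translation factor, stood at 253 against 93.6 RPKM and TFB2M, a mitochondrial transcription factor, at 44.8 against 16.8 RPKM. The cytosolic ribosomal proteins went the other way, with a median of 0.29 over 65 members, at percentile 100, although 63 of them lay within 2-fold. The 2 beyond it were RPL7A, at 2215 against 8644 RPKM, and RPS20, at 1412 against 3121 RPKM, and both genes host snoRNAs in their introns. Proteasome subunits had a median of -0.46 over 28 members at percentile 0.2, and PSMB5, a catalytic subunit, was the 1 member at least 2-fold lower, at 1015 against 429 RPKM. PSMD12, PSMB2 and PSMD7 were 1.88-fold, 1.84-fold and 1.82-fold lower.

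KLK3, which encodes PSA, had its value in 1 row joined with its neighbour KLK2, at 1528 against 1675 RPKM, a log2 ratio of 0.13 (chromosome 19, 51358074 to 51383823). TMPRSS2, an androgen-induced protease, stood at 251 against 310 RPKM. Androgen receptor activated targets had a median of 0.07 over 46 expressed members, at percentile 91.2, with 3 at least 2-fold higher and 8 lower, and the sign turned to -0.02 with equal sums over the genes kept. The members with the largest differences were lower. They were KRT19, a keratin, at 23.1 against 1.84 RPKM, the ion channel TRPM8 at 40.8 against 6.42 RPKM, ALDH1A3, of retinoic acid synthesis, at 73.3 against 13.3 RPKM, and IQGAP2 at 27.4 against 4.89 RPKM. Of genes chosen after their values were seen, KLK4 was 2.79-fold higher at 285 against 798 RPKM and FKBP5 stood at 72.7 against 48.6 RPKM.

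Androgen receptor repressed targets were lower, with a median of -1.18 over 15 expressed members, below all random lists, and 10 at least 2-fold lower. SYT4, a synaptotagmin, was 15.8-fold lower at 143 against 8.11 RPKM. DDC, an aromatic amino acid decarboxylase, CXCR7, a chemokine receptor, and CAMK2N1 were 4.52-fold, 4.14-fold and 3.85-fold lower. Without the filter on low values the median was -0.28. The receptor's cofactors had a median of 0.29 over 18 members, at the edge of the random range at percentile 97.53, and fell inside it when random lists were matched in 20 bins. NCOA3 and PIAS1 were 2.05-fold and 1.81-fold higher in that list, and KDM1A and HOXB13 1.79-fold and 1.71-fold lower. Genes of androgen synthesis had a median of -0.18 over 7 members, at percentile 31.3, and HSD17B6 stood at 12.4 against 2.45 RPKM. Prostate lineage and tumour markers had a median of -0.34 over 21 members, at percentile 5.01, with 6 at least 2-fold lower and 1 higher. The noncoding RNAs PCA3 and PCAT1 stood at 18.8 against 0.540 and 5.25 against 1.18 RPKM, and ACPP, prostatic acid phosphatase, at 13.4 against 3.07 RPKM.

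The integrated stress response, the programme that ATF4 drives when amino acids or translation are limited, had a median of -0.95 over 42 expressed members, below all random lists. Of these, 18 were at least 2-fold lower, none was at least 2-fold higher and 24 lay within 2-fold. TRIB3 was at 45.8 against 11.8 RPKM and NUPR1 at 364 against 113 RPKM. CEBPG and STC2 were 3.01-fold and 2.86-fold lower. ATF4 itself, chosen after its values were seen, stood at 521 against 271 RPKM. Among other members chosen so, ASNS stood at 230 against 228 RPKM and DDIT3 at 77.7 against 90.3 RPKM, whereas MTHFD2 and CHAC1 were 2.76-fold and 2.41-fold lower. Targets of p53 had a median of -0.82 over 33 members, also below all random lists, with 13 at least 2-fold lower. SPATA18, FAS, PHLDA3 and AEN had the largest differences, at 8.43 against 1.05, 8.71 against 1.26, 14.2 against 3.24 and 14.2 against 3.94 RPKM. CDKN1A and MDM2, chosen after their values were seen, were 1.91-fold and 1.48-fold lower.

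Other stress and survival lists lay within the random range. Unfolded protein response genes had a median of -0.16 at percentile 31.5, although CREB3L4 and XBP1 were 3.89-fold and 2.35-fold lower and the chaperone HSP90B1 was 1.90-fold higher. Heat shock genes had a median of -0.37 at percentile 4.63, with HSPD1 2.04-fold and AHSA1 1.89-fold lower. Oxidative stress genes had a median of -0.23 at percentile 17.7, with the cystine transporter SLC7A11 and HMOX1 2.23-fold and 2.04-fold lower. CDK inhibitors and arrest genes had a median of -0.19 at percentile 21.9, and GADD45A was 2.73-fold lower. Pro-apoptotic BCL2 family genes had a median of -0.46 at percentile 3.99, with PMAIP1 at 8.01 against 3.42 RPKM. The anti-apoptotic genes had a median of -0.40 over 8 members at percentile 9.27, and among them BIRC5, BCL2L2 and XIAP were 4.21-fold, 3.59-fold and 2.78-fold lower.

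Cholesterol synthesis genes had a median of 0.32 over 22 expressed members, at percentile 99.5, with 3 at least 2-fold higher, 1 lower and 18 within 2-fold, and resampling of the members gave -0.00 to 0.45. INSIG1, a sensor of sterols, was at 91.1 against 328 RPKM and FDFT1, squalene synthase, at 632 against 1648 RPKM. EBP, a sterol isomerase, was the lower member, at 114 against 53.7 RPKM. Fatty acid synthesis genes had a median of 0.34 over 21 members, at percentile 99.05, again with 3 at least 2-fold higher and 1 lower, and resampling gave -0.03 to 0.70. SREBF1, the transcription factor of the pathway, was 3.58-fold higher at 198 against 711 RPKM, with a counting interval of the log2 ratio from 1.82 to 1.86. ACSL1 and FASN stood at 366 against 914 and 44.4 against 99.6 RPKM, while the elongase ELOVL5 was at 747 against 378 RPKM. Autophagy and lysosome genes had a median of 0.20 over 38 members, at percentile 98.8, with 4 at least 2-fold higher and 1 lower. The other 33 lay within 2-fold, and resampling gave -0.05 to 0.34. ULK1, the kinase that starts autophagy, was at 1.80 against 11.5 RPKM, the lysosomal protease CTSB at 38.0 against 81.6 RPKM and PLEKHM1 at 7.86 against 18.1 RPKM, while ATG9B was lower at 8.12 against 1.52 RPKM. Glycolysis and hypoxia genes had a median of 0.01 at percentile 71.2, and nuclear-encoded genes of oxidative phosphorylation one of -0.05 at percentile 62.7. The sign of both depended on the scaling, as did that of the medians near 0 of PI3K and FOXO genes, neuroendocrine genes, chromatin regulators, and Mediator and general transcription factors given below.

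**Figure D3:**
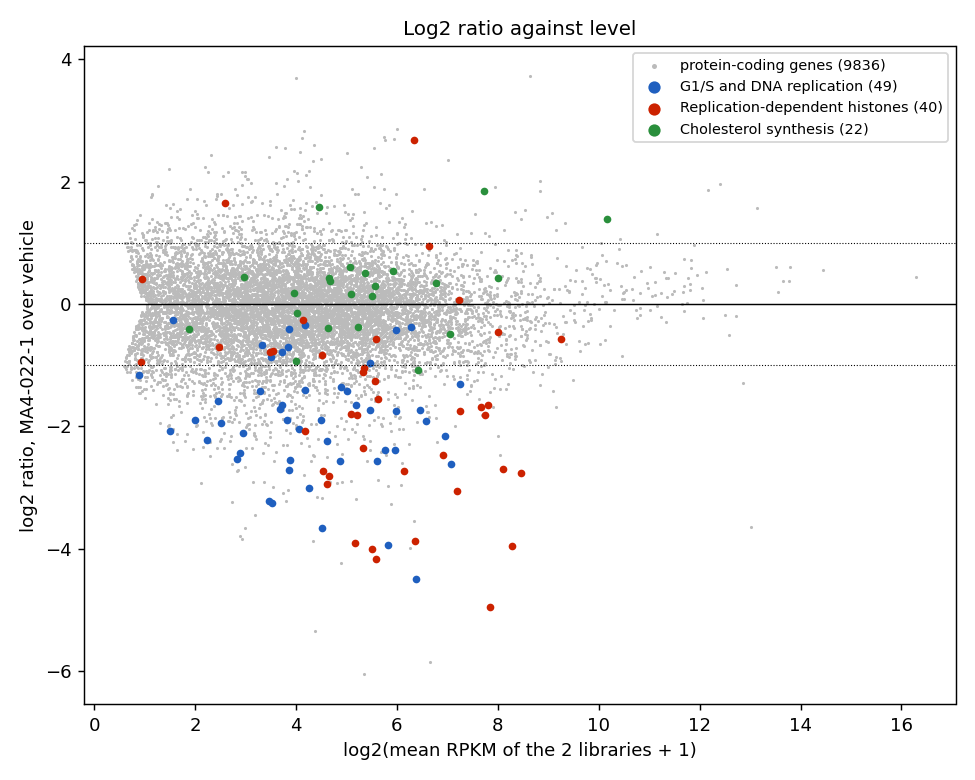
Log2 ratio of MA4-022-1 over vehicle against log2 of the mean RPKM + 1 of both libraries for 9836 protein-coding genes (grey), with the lists of G1/S genes (blue, 49), replication-dependent histones (red, 40) and cholesterol synthesis (green, 22) on top. Most blue and red points lie under the lower of the dotted lines, which mark 2-fold either way.

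Among signalling lists, interferon response genes had a median of -0.39 over 27 members at percentile 1.06, and TGF-beta and BMP targets one of -0.50 over 15 members at percentile 1.35. Both medians changed sign, to 0.06 and 0.12, when 5 RPKM was required in a library, and both lay within the random range of protein-coding genes. PARP9, DTX3L and ISG20 were 2.96-fold, 2.51-fold and 2.30-fold lower, whereas the antiviral gene MX1 was 2.65-fold higher. TGFB1 and PMEPA1 were 4.27-fold and 2.82-fold lower, and SKI and ID2 3.01-fold and 2.63-fold higher. The medians of immediate early genes, ERK feedback genes, JAK and STAT targets, and PI3K and FOXO genes were -0.16, -0.48, 0.20 and 0.03, all within the random range. FOS was 3.26-fold and DUSP4 2.45-fold lower, and JAK1 and IGF1R were 2.55-fold and 2.38-fold higher. Antigen presentation, NF-kB, Wnt and Notch lists had medians of 0.09, 0.31, -0.33 and -0.31, also within the random range. With joined rows counted, an alternative chosen after seeing the data, the Notch median was 0.13 over 11 members instead of 9. B2M was 2.10-fold higher, IL32 5.15-fold lower, LRP6 1.52-fold higher and HES1 2.15-fold lower.

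Chromatin regulators had a median of 0.05 over 62 expressed members, at percentile 83.5, and 58 were within 2-fold. ATAD2 and EZH2, which are genes of proliferating cells, were 2.73-fold and 2.53-fold lower, and the histone demethylase KDM6B 3.06-fold higher. Mediator and general transcription factors had a median of -0.01 over 45 members, with POLR2A, the largest subunit of RNA polymerase II, at 10.1 against 31.8 RPKM and POLR2L at 109 against 246 RPKM. Splicing factors had a median of 0.15 over 30 members at percentile 97.38, just inside the random range, and outside the range of protein-coding genes. HNRNPA1 and SRSF7 were 2.49-fold and 2.05-fold lower, and SF3A1 1.88-fold higher. Long noncoding RNAs had a median of -0.14 over 11 members, with 3 at least 2-fold lower and 2 higher, and one of 0.40 over 18 members when joined rows were counted, an alternative chosen after seeing the data. The higher ones were nuclear RNAs. NEAT1, the scaffold of paraspeckles, stood at 91.8 against 641 RPKM (chromosome 11, 65190224 to 65213604) and MALAT1 at 985 against 3659 RPKM.

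Epithelial junction genes, mesenchymal genes and neuroendocrine genes had medians of -0.18, -0.15 and -0.02, within the random range, and the last became 0.35 when joined rows were counted. OVOL2 was 2.81-fold lower, ELF3 stood at 11.2 against 4.56 RPKM, FN1 at 38.8 against 22.6 RPKM and COL1A1 at 1.19 against 5.03 RPKM. Housekeeping controls had a median of -0.12 over 25 members at percentile 41.5, with GAPDH, chosen after its values were seen, at 1311 against 1227 RPKM, while B2M was 2.10-fold higher. Listed markers of other cells that had a row of their own were low in both libraries. None of 15 leukocyte markers and none of 11 endothelial markers with a row reached 1 RPKM, and 2 of 13 fibroblast markers did, ACTA2 at 2.75 against 3.13 RPKM and COL1A1. Of markers of the PC-3 and DU145 lines, 2 of 15 did, LGALS1 at 5.08 against 4.34 RPKM and VIM at 2.97 against 2.60 RPKM. Only 2 basal prostate markers were expressed, ITGA6 at 12.8 against 11.8 RPKM and DST at 6.54 against 6.52 RPKM. Of the list for bone metastasis 4 genes were expressed, with BMP7 at 3.50 against 1.44 RPKM. With joined rows counted, an alternative chosen after seeing the data, 1 leukocyte marker was expressed. So were 3 fibroblast markers, 3 basal markers and 5 genes of the bone list.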

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

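The tests of reads behind extreme rows, of genes split by their reads, of scale, of reads behind histone rows and of both explanations for the mitochondrial rows were chosen after the results were seen, and those of counting intervals, small RNA hosts and short transcripts before.

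Rows that the main comparison left out held signal in both libraries, and 3 sets of them held rows above their vehicle level. The 5 unnamed rows on the mitochondrial chromosome had a median ratio of 2.32 between MA4-022-1 and vehicle, from 2.07 to 3.21. The row covering positions 1 to 1511 went from 143 to 389 RPKM. Positions 1608 to 4572 and 4625 to 16571 each recurred among the rows, so the rows are not all separate stretches of the chromosome. Among 2746 unnamed rows at 1 RPKM or more, 1017 were at least 2-fold higher and 591 lower, while unnamed rows held 29.6% of the summed RPKM in the vehicle library and 23.3% with MA4-022-1. Among 355 short RNA symbols at that level, 130 were at least 2-fold higher and 91 lower, and these symbols entered only the alternative that kept them.

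For the mitochondrial rows, a general increase of genes for the respiratory chain is argued against by the nuclear-encoded list, whose median log2 ratio was -0.05. A difference in the removal of ribosomal RNA between the libraries cannot be told apart from a change in the cells. The abundant 28S row had a ratio of 1.11, but the 45S precursor row had one of 2.69 and a 5.8S-like row one of 1.72, so the ribosomal rows do not go together. A biological difference through the treatment stays open and untested, since each group has 1 library.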

How the results depend on the processing

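The alternatives on protein-coding genes, snoRNA hosts, values above 0 in both libraries, single-row or shared list members and joined rows were chosen after seeing the data. Counting all expressed symbols with a single row was planned. No paired analysis was possible because each group holds 1 library. With a pseudocount of 0.1, 1951 genes were at least 2-fold higher, and with one of 5, 437 were higher and 662 lower, where the list medians became -0.64 for androgen receptor repressed targets, -1.39 for G1/S and -1.04 for G2/M genes. Requiring 5 RPKM left 739 higher genes and turned the medians of interferon response to 0.06 and of TGF-beta and BMP targets to 0.12. Without a filter, androgen receptor repressed targets had -0.28 and histones -0.81. At 1.5-fold, 2902 genes were higher and 3191 lower, and at 4-fold 208 and 291. Protein-coding symbols with a single row gave 334 and 853. With housekeeping controls set to 0, the median of expressed genes was 0.10 and that of G2/M genes -1.36. The median of genes raised by BET inhibitors turned to -0.22 over single-row members. The cause was not tested where the setting does not itself remove genes or compress low values. Over all alternatives, 646 list medians stayed within the resampling interval of their members, 13 moved beyond it and 3, of lists outside the random range, changed sign. Those that stayed include the medians under matching in 20 bins and under random lists of protein-coding genes. These settings change only the random lists, so no list median could move under them. Another 25 with the other sign are among those that stayed or moved. Of the log2 ratios of named genes, none of those beyond 2-fold changed sign. With a counting interval, 720 stayed within it and 450 left it, and without one, 33 moved by less than 0.1 and 51 by more. Matching in 20 bins changed 1 call and random lists of protein-coding genes 3. The alternative that needs intervals per gene was not run, since the tables analysed here hold none. Depth limits low genes, since 3 reads at 2000 nt are worth 0.0838 RPKM in the MA4-022-1 library.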

Other observations

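The tests of reads behind extreme rows, of genes split by their reads, of scale and of reads behind histone rows were chosen after the results were seen, as were all genes named in the next paragraph.

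Among the 20 lowest protein-coding genes with a single row, CA1, a carbonic anhydrase, was 18.8-fold lower at 55.5 against 2.01 RPKM, and FAM111B and ZNF367 were 14.6-fold and 10.9-fold lower. Among the 20 highest were SPAG8, at 1.28 against 28.6 RPKM, EPC1, a chromatin protein, at 13.1 against 91.7 RPKM, and the neuronal microtubule gene MAP2 at 4.16 against 27.9 RPKM. Within the splicing list, 28 of 30 members lay within 2-fold and 2 were at least 2-fold lower. The members named here lay within 2-fold and went in different directions. The kinases CLK2, CLK3 and CLK4, which phosphorylate SR proteins, stood at 21.9 against 37.4, 80.0 against 138 and 11.1 against 19.2 RPKM, while HNRNPA2B1 and SRSF3 stood at 599 against 393 and 243 against 155 RPKM. The variant histones H2AFZ, H3F3A and H3F3B, made outside S phase as well, had log2 ratios of -0.81, -0.23 and 0.37, against -1.71 for the median of the replication-dependent list.

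The lower replication-dependent histone rows were weighed against technical explanations. Loss of short transcripts in the MA4-022-1 library is argued against by 209 other protein-coding genes with a median annotated transcript under 700 nt, whose median log2 ratio was 0.08. Under 4 other scalings, which shifted the median of expressed genes by -0.09 to 0.12, the highest histone median was -1.60. Shifts of that size do not account for the lower histone rows, and a larger difference in scale was not tested. The 37 histone genes with at least 100 estimated reads over both libraries had a median of -1.79, from -2.70 to -1.11 when members were resampled. They were 37 of the 40 with a read estimate, so this median could hardly differ from that of the list. That share shows only that most of the histone genes did not rest on few reads. No biological mechanism was tested. A difference through the treatment stays open, as does one between the 2 cultures that is not due to the compound, since each group has 1 library.

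For rows at the extremes and beyond 2-fold, 58.3% of the 24 most extreme genes held a value that recurs exactly in another row of its library, against 3.15% of 7076 protein-coding genes with a single row and at least 5 RPKM. Recurring values would go with few reads on short features, but the 12 of these genes with an annotated length had from 53 to 4502 estimated reads in the higher library. The lengths of the deposited features are not known, so few reads behind these rows cannot be told apart from a difference in the cells. AC095064.1, among the lowest, and AC105316.1, among the highest, share a deposited locus (chromosome 4, 160025222 to 160281321). The former was at 120 RPKM in the vehicle library and listed at 0 with MA4-022-1. The latter was listed at 0 and at 58.1 RPKM. How reads were assigned between features of a shared locus was not tested. Among 1338 protein-coding genes beyond 2-fold with an annotated length, 100% had a counting interval that excluded no change, which decides nothing, since 99.3% of them would at exactly 2-fold. Of all 4552 protein-coding genes with at least 2000 estimated reads over both libraries, whatever their ratio, 11.6% lay beyond 2-fold, and of all 4370 with 200 to 2000 such reads 15% did. Of all 911 with under 200 reads 17% did, with a binomial interval from 14.6% to 19.5%, and within that set the share was 17.7% with 100 to 200 and 15.3% with under 50. This argues against counting error alone, although single genes with few reads stay uncertain. Hosts of snoRNAs made up 1.73% of the protein-coding genes at least 2-fold higher and 1.28% of all protein-coding genes. Those shares argue against snoRNA reads in introns as a main source of the higher genes. Hosts of other small RNAs were not examined.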
